A study of Mus musculus with 15 samples.

How the data were processed

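Values of 45101 probe sets on 15 arrays were taken as deposited, on the log2 scale. Their range and distribution are those of RMA, which the submitters' processing notes name together with MAS5, without versions or roles; whether both sets of arrays were normalized together is not stated. Per the labels the arrays fall into 5 groups of 3, in 2 sets that each hold their own DMSO arrays. The number of arrays limits the precision.

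Probe sets were matched to gene symbols with the platform's annotation table: 34945 had 1 symbol, 932 had several and were left out, and 9160 had none and were tested on their own. Controls (64) were left out. Where a gene had more than 1 probe set, as 9010 genes did, the probe set with the highest mean over all arrays was used, which gave 18193 genes.

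A linear model with 5 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with 10 residual and 4.33 prior degrees of freedom, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Fold changes are coded treated minus DMSO of the same set, and the SE is that of the moderated fit. The 8 comparisons were PHA, ICG and PHA+ICG against DMSO, PHA against ICG, the effect of PHA+ICG minus that of PHA and minus that of ICG, the departure from additivity, and DMSO of the second set minus DMSO of the first. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.

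Before the data were examined, 25 gene lists were written: Wnt and β-catenin targets, MET and ERK output, G1/S and DNA replication, G2/M and mitosis, luminal, basal, milk protein, squamous, stem and progenitor, mesenchymal, CXCL12 and HGF axis, p53 targets, ATF4 response, ER chaperones, cholesterol biosynthesis, glycolysis and hypoxia, AhR targets, NRF2 targets, interferon response, NF-kB, MYC and ribosome biogenesis, and markers of fibroblasts, endothelial cells, leukocytes and adipocytes. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. P-values were adjusted over the 25 lists of a comparison. Lists could share members, such as Sesn2 (p53 targets and ATF4 response) and Slc7a11 (ATF4 response and NRF2 targets), so their results are not independent. The comparisons, alternatives and the rule for named genes were also fixed before the data were examined. In the milk protein list the written symbol Trf was matched through a synonym to Trh, a hormone gene. That tested member is therefore not the gene that was meant.

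The rule named the 10 highest and 10 lowest called genes of each main comparison (5 and 5 of the others) with all 3 treated arrays beyond all 3 controls where 2 groups are compared, passing over clone-like symbols. It added up to 4 called members of each list that camera called or that had at least 3 called members, and 24 genes fixed in advance, of which Ccnb1 had no probe set for that gene alone and was not measured. The text gives a selection of these.

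Replicate numbers were checked for pairing through the correlation of deviations from the group means. In the first set same-numbered arrays correlated between −0.26 and 0.12, so they were not treated as pairs. In the second set the 3 correlations were 0.61, 0.36 and 0.28, all above 0.1, so its same-numbered arrays were taken as pairs and fits with replicate number as a block are given beside the fit without a block, which had been fixed beforehand. Arrays 2 and 3 also correlated across numbers to a similar degree (0.24 and 0.35), and the labels do not say what a number shares.

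The procedure was tested on simulated data with the observed spread of each set. A change of 1 on the log2 scale was recovered for 86.5% of changed genes with PHA, 84.8% with ICG and 89% with PHA+ICG; of the calls 1.26%, 0.819% and 67.8% were false. With no change the fit called 0 genes with PHA and with ICG and from 229 to 266 with PHA+ICG, because the second set spread 2.22 times as much as the first. These simulated arrays were independent. Where same-numbered arrays of the second set shared 0.326 of their variance, the consensus correlation of its pairs, the fit called 41.45 genes on average with no change, and 38.4% of the calls were false where 200 genes changed; with the block in the second set it called 616.45. Its spread was 1.72 times that of the first set once the pairs were blocked. A fit of the second set alone made no call in 20 such runs without change, with or without the block. With the block it recovered 0% of genes changed by 1 where 200 changed, and 100% of its calls there were false. These runs therefore cannot tell how many calls of this fit in the real data are false. Because the pooled fit made false calls for PHA+ICG, the named genes and called lists of PHA+ICG are also described on the second set alone. This was done without the block and with its pairs. Without the block 24.7% of genes changed by 1 were recovered there where pairs shared their deviations. Comparisons of effects across sets are also given with array weights by set, which do not remove false calls. In the runs with shared deviations 12.2% of their PHA+ICG calls were false where 200 genes changed, and 37.5% with the block. With no change they called 2 and 29 genes on average.

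The alternatives were quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set on its own, a trended robust fit, array weights, a replicate block, all 6 DMSO arrays as control, each set fitted alone, a fold-change minimum, and leaving out each array in turn. Added after the data were seen were array weights by set, the block in the second set alone, leaving out both arrays numbered 1 of the second set, the second set alone and weights by set with that block, and tests of probe sets with no symbol. Other splits of the arrays into groups of the same sizes were counted for each comparison.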

Results

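Gene expression was measured on 15 Affymetrix mouse arrays of mammospheres, which are spheres that mammary cells form in non-adherent culture. The cells came from primary mammary tumours of FVB/N mice whose genotype is written WAPCre-DNbcatn;HGF, a name that holds HGF, the ligand of the MET receptor. The spheres grew for 7 days, were treated for 24 h, and gave 250 ng of RNA per array. The labels place 9 arrays in a first set, with 3 DMSO, 3 PHA and 3 ICG arrays, and 6 arrays in a second set, with 3 DMSO and 3 PHA+ICG arrays. The series text speaks of Wnt and MET pathway inhibitors. By general knowledge rather than by the labels, PHA is short for a MET kinase inhibitor and ICG for an inhibitor of β-catenin-driven transcription, and no full names or doses are given. The number of arrays limits the precision of every value below. The labels do not say whether replicates were separate cultures or animals, so each p-value measures only the spread between these arrays, which may be technical. Unless another error is named, values are log2 fold changes ± SE with n = 3 arrays in each of the groups compared. The SE and p-values rest on a spread pooled over all 15 arrays, not on that of the groups compared alone. The second set spread 2.22 times as much as the first. SE and p-values are therefore mostly too small for PHA+ICG and mostly too large for PHA and ICG.

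PHA against DMSO asks which genes respond to a block of MET signalling in these spheres. PHA lowered Arg1, which encodes the urea-cycle enzyme arginase, by a log2 fold change of −3.18 ± 0.28 (adjusted p = 8.07e-05). Mmp1a, a secreted collagenase, fell by 2.92 ± 0.17 on the log2 scale (adjusted p = 1.24e-06), and Postn, a matrix protein of stromal cells, changed by −2.33 ± 0.33. Fcer1a, the alpha chain of the high-affinity IgE receptor, changed by −2.90 ± 0.19, the protease gene Mcpt8 by −2.19 ± 0.30, and Tph1, which makes the serotonin precursor, by −2.24 ± 0.21. Cemip, which acts in hyaluronan breakdown, changed by −2.14 ± 0.22, Nptx1 by −2.10 ± 0.27, the chemerin gene Rarres2 by −2.20 ± 0.37, and the microfibril gene Mfap5 by −2.03 ± 0.13. The increases were smaller. Lgi3 changed by 1.08 ± 0.12 (adjusted p = 0.00032), the immediate early transcription factor gene Egr1 by 1.02 ± 0.14, the histone gene H2bc22 by 0.80 ± 0.11, and the transcobalamin receptor gene Cd320 by 0.79 ± 0.12. The sterol and lipid synthesis genes Tm7sf2, Idi1 and Fads2 changed by 0.80 ± 0.17, 0.69 ± 0.12 and 0.68 ± 0.13, Cenpm by 0.74 ± 0.13, Prss16 by 0.74 ± 0.16, and the metalloproteinase inhibitor gene Timp1 by 0.70 ± 0.13. For each of these 20 genes all 3 PHA arrays lay beyond all 3 DMSO arrays, as the rule that picked them required. The calls of Tm7sf2 and Prss16 were lost whichever of the 6 arrays was left out, and those of Cenpm, Timp1, Idi1, Fads2 and Rarres2 without at least 1 of the 6.

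Fibroblast markers were lower with PHA: 4 of 16 fell and the other 12 did not pass, with a mean of −0.82 and a camera adjusted p of 1.42e-15. Adjusted over the list alone 10 fell, as many fell on the first set alone, and the list's adjusted p = 0.106 with an estimated correlation. Besides Postn and Mfap5, the collagen gene Col3a1 changed by −1.54 ± 0.32 and the fibulin gene Fbln2 by −0.63 ± 0.10, and both calls were lost without at least 1 array. Cholesterol biosynthesis genes were higher, with 2 of 20 called (Tm7sf2 and Idi1), a mean of 0.27 and a camera adjusted p of 4.38e-06. Adjusted over the list alone 5 of the 20 rose, on the first set alone 7, and the list's adjusted p = 0.13 with an estimated correlation. Squamous differentiation genes had a mean of −0.49 and a camera adjusted p of 8.83e-07. By limma, 0 of the 28 passed over all genes, 11 had an unadjusted p under 0.05, 9 fell adjusted over the list alone and 18 on the first set alone; adjusted p = 0.403 with an estimated correlation. Basal and myoepithelial markers had a mean of −0.37 and a camera adjusted p of 0.000152. By limma 0 of the 20 passed, 7 had an unadjusted p under 0.05, 4 fell adjusted over the list alone and 8 on the first set alone; adjusted p = 0.106 with an estimated correlation. Among them Krt14 was at −0.70 ± 0.22 and Krt5 at −0.65 ± 0.19, both short of the threshold in the pooled fit. Mesenchymal transition genes had a mean of −0.32 and a camera adjusted p of 0.000304. By limma 0 of the 19 passed, 8 had an unadjusted p under 0.05, 1 rose and 6 fell adjusted over the list alone, and 1 rose and 8 fell on the first set alone; adjusted p = 0.18 with an estimated correlation.

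Camera also called ATF4 and integrated stress response genes lower with PHA, at a mean of −0.23 with 1 of 26 called, the stanniocalcin gene Stc2 at −0.88 ± 0.19. Adjusted over the list alone 4 fell, on the first set alone 8, and the list's adjusted p = 0.425 with an estimated correlation. ER chaperones and XBP1 targets were called lower at a mean of −0.13 with 1 of 18 called, Manf at −0.41 ± 0.09, and 4 lower on the first set alone (list adjusted p = 0.425 with an estimated correlation). The calls of Stc2 and Manf were lost whichever of the 6 arrays was left out, and with quantile normalization or median centring. G1/S and DNA replication genes (mean −0.16, 4 of 35 at unadjusted p under 0.05), p53 targets (mean −0.17, 3 of 19) and MYC and ribosome biogenesis genes (mean −0.12, 2 of 22) were called lower by camera with 0 members called by limma over all arrays. On the first set alone 6 G1/S genes fell, 6 p53 targets fell and 1 rose, and 4 MYC genes fell. Their p-values with an estimated correlation were adjusted p = 0.425, 0.425 and 0.513, and the call of the G1/S genes was lost without DMSO replicate 3 (mean −0.08), while the mean was −0.25 without DMSO replicate 1 and −0.10 without PHA replicate 3. MET and ERK output genes were called lower at a mean of −0.11 (camera adjusted p = 0.0269), although their 1 called member, Egr1, rose; on the first set alone limma called 2 of the 27 higher and 10 lower. This call was lost with an estimated correlation (adjusted p = 0.453), with quantile normalization (mean −0.06), and without DMSO replicate 1 (−0.09), PHA replicate 1 (−0.10) or PHA replicate 2 (−0.08). Of 29 Wnt and β-catenin targets limma called 0, with 3 at an unadjusted p under 0.05, a mean of −0.06 and a camera adjusted p of 0.299; 2 were lower on the first set alone. G2/M genes had a mean of −0.06, with 0 of 36 called by limma and 0 at an unadjusted p under 0.05, but camera called them lower without DMSO replicate 1 (mean −0.28) or PHA replicate 1 (−0.15). Met itself was at −0.35 ± 0.24, its feedback target Dusp6 at 0.23 ± 0.14 and Myc at −0.44 ± 0.16, and none of the 3 passed.

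With PHA, limma called 182 of 18193 genes at an adjusted p under 0.05, of which 18 were higher and 164 lower; 2 of the higher and 74 of the lower genes changed at least 2-fold. At an unadjusted p under 0.05 there were 1611 genes, and the 2 groups did not overlap for 31.6% of genes, where chance gives 10%. The share of higher calls moved with scaling: 40 rose and 148 fell with quantile normalization, and 39 rose and 125 fell with each array centred on its median. Fitted on the arrays of the first set alone, whose replicates spread less, limma called 1858 genes, 572 higher and 1286 lower, a larger share of them higher than in the pooled fit. Leaving out 1 array gave 82 (DMSO 2), 92 (DMSO 3), 93 (PHA 1), 75 (PHA 2) or 104 (PHA 3) calls.

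**Figure D1:**
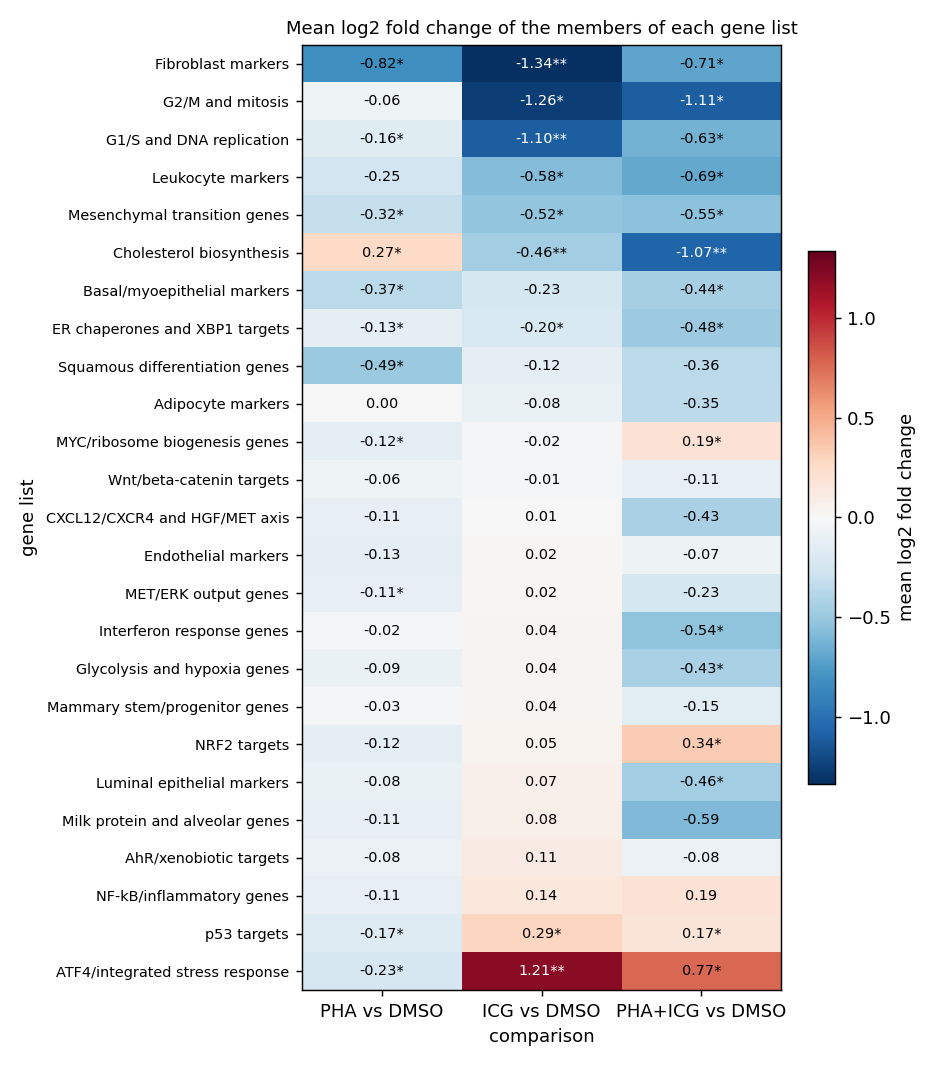
Mean log2 fold change of the members of each of the 25 gene lists (vertical axis) in PHA, ICG and PHA+ICG against the DMSO arrays of the same set (horizontal axis), with * for a camera call and ** for a call that also held with an estimated correlation. Cholesterol biosynthesis genes were at 0.27 with PHA, −0.46 with ICG and −1.07 with PHA+ICG.

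ICG against DMSO asks which genes respond to a block of β-catenin-driven transcription. With ICG, Cth, which makes cysteine from cystathionine, changed by 3.34 ± 0.22 (adjusted p = 1.46e-06), the serine synthesis gene Psat1 by 2.33 ± 0.16, the asparagine synthetase gene Asns by 2.18 ± 0.14, and the amino acid transporter genes Slc7a3 and Slc7a5 by 2.94 ± 0.55 and 1.93 ± 0.19. The stress-induced genes Trib3, Niban1 and Chac1 changed by 2.10 ± 0.30, 2.05 ± 0.15 and 1.95 ± 0.36, the secreted carbonic anhydrase gene Car6 by 3.17 ± 0.48, and the actin-binding protein gene Avil by 1.96 ± 0.27. The calcium-binding protein gene S100a4 changed by −3.50 ± 0.25 (adjusted p = 1.89e-06), the DNA topoisomerase gene Top2a by −3.48 ± 0.30, the ribonucleotide reductase gene Rrm2 by −3.24 ± 0.29, and the mitotic genes Anln and Ube2c by −3.09 ± 0.40 and −3.04 ± 0.29. Arg1 changed by −3.42 ± 0.28, the chemokine gene Ccl12 by −3.39 ± 0.42, Crabp1 by −3.24 ± 0.52, the integrin gene Itga8 by −3.22 ± 0.36, and Cthrc1, a secreted matrix-associated protein gene, by −3.02 ± 0.38. For each of these 20 genes all 3 ICG arrays lay beyond all 3 DMSO arrays, as the rule that picked them required.

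Of 26 ATF4 and integrated stress response genes, 19 rose with ICG and the other 7 did not pass (mean 1.21, camera adjusted p = 1.33e-29). Adjusted over the list alone 22 rose, and the list's adjusted p = 0.0137 with an estimated correlation. G1/S and DNA replication genes fell in 23 of 35 cases (28 adjusted over the list alone; mean −1.10, camera adjusted p = 3.69e-33), at an adjusted p of 0.0111 with an estimated correlation. The replicative helicase genes Mcm5 and Mcm6 changed by −2.67 ± 0.20 and −2.34 ± 0.16, and Uhrf1, a maintenance factor of DNA methylation, by −2.53 ± 0.24. Of 36 G2/M and mitosis genes 24 fell (31 adjusted over the list alone; mean −1.26, camera adjusted p = 9.63e-30), with an adjusted p = 0.0644 with an estimated correlation. Birc5, the gene for survivin, changed by −2.98 ± 0.23 and the checkpoint kinase gene Bub1 by −2.75 ± 0.40, while Mki67, at −1.04 ± 0.31, did not pass (adjusted p = 0.0652). The per-array means of the G2/M genes were 6.23, 6.75 and 7.00 in DMSO and 5.53, 5.31 and 5.35 in ICG. Fibroblast markers fell in 13 of 16 cases (15 adjusted over the list alone; mean −1.34, camera adjusted p = 1.65e-17), at an adjusted p of 0.0331 with an estimated correlation. Col3a1, Postn, Col1a1 and Col6a3 changed by −2.49 ± 0.32, −2.34 ± 0.33, −2.31 ± 0.26 and −2.30 ± 0.22. Cholesterol biosynthesis genes fell in 6 of 20 cases (11 adjusted over the list alone; mean −0.46, camera adjusted p = 2.13e-09), at an adjusted p of 0.0331 with an estimated correlation. The squalene synthase gene Fdft1, the farnesyl diphosphate synthase gene Fdps, Idi1 and Stard4 changed by −1.23 ± 0.15, −1.21 ± 0.17, −1.08 ± 0.12 and −0.97 ± 0.18.

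Mesenchymal transition genes fell in 4 of 19 cases with ICG (mean −0.52), S100a4 apart the transcription factor genes Twist2 and Zeb1 by −2.06 ± 0.27 and −0.98 ± 0.17; the list's adjusted p = 0.0819 with an estimated correlation. Leukocyte markers fell in 4 of 20 cases (mean −0.58, camera adjusted p = 0.0371), at an adjusted p = 0.64 with an estimated correlation. The complement gene C1qb changed by −2.75 ± 0.49, and C1qc, Cd52 and Aif1 by −2.19 ± 0.56, −1.52 ± 0.43 and −0.99 ± 0.26. The last 3 calls were lost without at least 1 array, those of Cd52 and Aif1 also with quantile normalization, and the list's call was lost without DMSO replicate 3 (mean −0.54) or ICG replicate 3 (−0.52). Of 19 p53 targets 2 rose, the stress-response genes Sesn2 at 1.10 ± 0.14 and Trp53inp1 at 0.86 ± 0.21 (list mean 0.29, adjusted p = 0.356 with an estimated correlation). Sesn2 is also a member of the ATF4 list, and the call of Trp53inp1 was lost whichever array was left out. ER chaperones and XBP1 targets were called lower (mean −0.20), with 3 of 18 falling, the disulfide isomerase gene Pdia4 by −1.17 ± 0.14 among them, and 1 rising (adjusted p = 0.417 with an estimated correlation). Camera did not call NRF2 targets, of which 5 of 16 rose and 2 fell, Gsta4 by −2.33 ± 0.28, but it called them higher without DMSO replicate 1 (mean 0.12) or ICG replicate 1 (0.08). Of 29 Wnt and β-catenin targets 2 fell (mean −0.01, camera adjusted p = 0.875), and Axin2, a widely used target, was at −0.17 ± 0.09, Ccnd1 at −0.09 ± 0.17 and Ctnnb1 at 0.28 ± 0.08, all short of the threshold. Of 27 MET and ERK output genes 2 rose, Egr1 by 0.87 ± 0.14 among them, and 1 fell (mean 0.02, camera adjusted p = 0.975). As a measure of RNA quality, the Actb signal at the 3′ end exceeded that at the 5′ end by 0.447 ± 0.124 (SD, n = 3, log2) in the DMSO arrays, 0.541 ± 0.0562 in PHA and 0.631 ± 0.0697 in ICG.

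With ICG, limma called 1255 genes, 384 higher and 871 lower, of which 65 and 263 changed at least 2-fold. At an unadjusted p under 0.05 there were 3367, and the groups did not overlap for 40.6% of genes, against 10% by chance. With quantile normalization 651 rose and 882 fell, and with each array centred on its median 621 rose and 727 fell. On the first set alone limma called 4896 genes, 2162 higher and 2734 lower, again with a larger share higher. Of the lists above, p53 targets then had 9 members higher, mesenchymal genes 2 higher and 10 lower, leukocyte markers 1 higher and 10 lower, and ER chaperones 3 higher and 11 lower. Wnt targets had 3 higher and 3 lower, and MET and ERK output genes 5 higher and 6 lower. Leaving out 1 array gave 667 (DMSO 2), 700 (DMSO 3), 678 (ICG 2) or 705 (ICG 3).

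**Figure D2:**
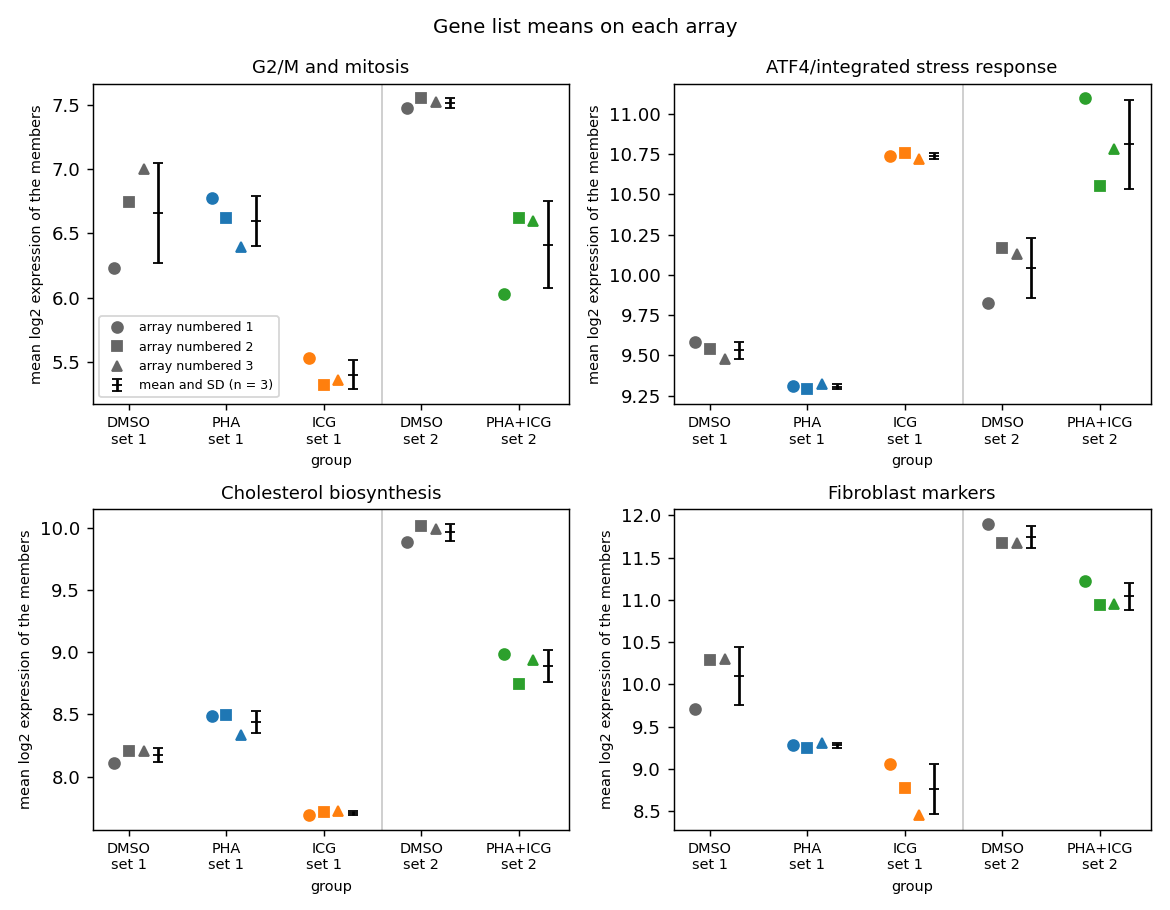
Mean log2 signal per array (points) of the G2/M, ATF4, cholesterol biosynthesis and fibroblast lists in the 5 groups, with the group mean and SD (n = 3). The 3 ICG arrays lay between 5.31 and 5.53 for the G2/M genes, below the 3 DMSO arrays of their set.

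PHA+ICG against the DMSO arrays of the second set asks what both inhibitors do together. The combination raised Car6 by a log2 fold change of 3.64 ± 0.48 (adjusted p = 0.000192), the mitochondrial protein gene Chchd10 by 2.76 ± 0.10 (adjusted p = 2.16e-09), the neural adhesion genes Tenm4 and Nrcam by 3.02 ± 0.23 and 2.65 ± 0.25, Trib3 by 2.49 ± 0.30 and the endothelin receptor gene Ednrb by 2.39 ± 0.19. Prr32, Mei4, Dlg2 and Avil changed by 3.12 ± 0.30, 2.70 ± 0.27, 2.55 ± 0.16 and 2.45 ± 0.27. The angiotensin receptor gene Agtr2 changed by −3.69 ± 0.25 (adjusted p = 1.06e-06), the amine oxidase gene Aoc3 by −3.40 ± 0.25, Arg1 by −3.34 ± 0.28, the collagen gene Col11a1 by −3.30 ± 0.46, the imprinted non-coding RNA gene Rian by −2.99 ± 0.20, Nrk by −2.51 ± 0.26 and S100a4 by −2.51 ± 0.25. Same-numbered arrays of the second set deviated alike (correlations of 0.61, 0.36 and 0.28), so fits that take them as pairs are also given. Arrays 2 and 3 correlated across numbers to a similar degree (0.24 and 0.35), and the labels name no pairs. A call that passes only with the pairs thus rests on a pairing taken from these same data. All 17 of these genes were also called on the arrays of the second set alone, with and without the pairs. The casein gene Csn2 (−4.33 ± 1.18), Ear3 (−3.51 ± 0.74) and the eotaxin gene Ccl11 (−2.58 ± 0.52) passed with the spread pooled over all arrays, but on the second set alone their adjusted p-values were 0.247, 0.119 and 0.0984, or 0.000495, 0.00321 and 9.65e-05 with the pairs. The call of Csn2 was also lost without at least 1 array. For each of these 20 genes all 3 PHA+ICG arrays lay beyond all 3 DMSO arrays, as the rule that picked them required.

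Cholesterol biosynthesis genes fell in 19 of 20 cases with PHA+ICG, and all 20 fell adjusted over the list alone (mean −1.07, camera adjusted p = 1.22e-22). The adjusted p = 0.00394 with an estimated correlation, and 10 fell on the second set alone, 17 with its pairs. Fdps, Tm7sf2, Fdft1 and Idi1 changed by −1.94 ± 0.17, −1.75 ± 0.17, −1.71 ± 0.15 and −1.58 ± 0.12. These 4 genes, and each other gene named with these lists, were also called on the second set alone. Of 36 G2/M and mitosis genes 26 fell (30 adjusted over the list alone; mean −1.11), 18 of them on the second set alone (27 with its pairs), with Ccnb2, Top2a, Mki67 and Birc5 at −2.13 ± 0.33, −2.10 ± 0.30, −2.07 ± 0.31 and −1.93 ± 0.23. Of 35 G1/S genes 19 fell (mean −0.63), 7 of them on the second set alone (17 with its pairs), with Mcm5 at −1.76 ± 0.20. ATF4 and integrated stress response genes rose in 16 of 26 cases (17 adjusted over the list alone; mean 0.77), 5 of them on the second set alone (14 with its pairs), among them Cth at 2.04 ± 0.22 and the cystine transporter gene Slc7a11 at 1.27 ± 0.14. ER chaperones and XBP1 targets fell in 9 of 18 cases and 1 rose (mean −0.48), and 6 fell on the second set alone. The protein-folding genes Pdia4, Sdf2l1, Pdia6 and Calr changed by −1.51 ± 0.14, −1.30 ± 0.18, −1.19 ± 0.13 and −1.18 ± 0.13. Camera called these 4 lists at adjusted p = 2.96e-19, 5.16e-11, 4.24e-14 and 1.25e-05, and each had an adjusted p = 0.142 with an estimated correlation.

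Fibroblast markers fell in 6 of 16 cases with PHA+ICG (mean −0.71; adjusted p = 0.223 with an estimated correlation) and in 3 on the second set alone, 8 with its pairs: Col1a1 at −1.95 ± 0.26, Fap at −1.23 ± 0.24 and Mfap5 at −1.09 ± 0.13. Mesenchymal transition genes fell in 9 of 19 cases (mean −0.55) and interferon response genes in 7 of 22 (mean −0.54), both at an adjusted p = 0.142 with an estimated correlation. On the second set alone limma called 3 of the mesenchymal genes and 0 of the interferon genes, of which 7 had an unadjusted p under 0.05; with its pairs it called 7 and 6. Ifit2, an antiviral gene, was at −1.50 ± 0.23, with an adjusted p of 0.0508 on the second set alone and 0.00169 with its pairs. Glycolysis and hypoxia genes fell in 8 of 22 cases (mean −0.43; adjusted p = 0.372 with an estimated correlation), but on the second set alone limma called 0, with 8 at an unadjusted p under 0.05, and 5 with its pairs. The mean of this list was −0.68 without DMSO replicate 1 and −0.27 without PHA+ICG replicate 1, the arrays with the lowest signal of the list in their groups. NRF2 targets rose in 7 of 16 cases and 1 fell (mean 0.34; adjusted p = 0.335 with an estimated correlation), and the mean was 0.22 without PHA+ICG replicate 1. On the second set alone 6 rose, among them the heme oxygenase gene Hmox1 at 0.99 ± 0.15, Srxn1 at 1.08 ± 0.17 and the transporter gene Abcc4 at 1.21 ± 0.14. Luminal markers fell in 4 of 19 cases (mean −0.46; adjusted p = 0.336 with an estimated correlation) and basal markers in 3 of 20 (mean −0.44; adjusted p = 0.223 with an estimated correlation). The keratin genes Krt8 (−1.23 ± 0.35), Krt18 (−0.88 ± 0.25) and Krt14 (−1.29 ± 0.22) were not called on the second set alone, where limma called 0 luminal and 0 basal markers, with 4 and 5 at an unadjusted p under 0.05. With its pairs limma called 5 and 4, with Krt8 and Krt14 at adjusted p = 0.0262 and 0.0149 and Krt18 short of the threshold (0.0645). The calls of both lists were lost without PHA+ICG replicate 3 (means −0.28 and −0.33), the luminal mean was −0.73 with 9 members lower without PHA+ICG replicate 1, and the calls of Krt8 and Krt18 were lost without at least 1 array.

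Of 19 p53 targets 6 rose and 2 fell with PHA+ICG (mean 0.17), and of 22 MYC and ribosome biogenesis genes 5 rose and 1 fell (mean 0.19), both at an adjusted p = 0.415 with an estimated correlation. On the second set alone limma called 1 p53 target, which rose, and 0 MYC genes, of which 6 had an unadjusted p under 0.05; with its pairs 3 p53 targets rose and 1 fell, and 2 MYC genes rose. Without PHA+ICG replicate 1 both calls were lost (means 0.01 and 0.11), as they were without PHA+ICG replicate 3 (0.18 and 0.14), and without PHA+ICG replicate 2 the means were 0.33 and 0.31. The p53 call was also lost without DMSO replicate 2 (0.14), and the MYC call without DMSO replicate 1 (0.11). Leukocyte markers fell in 2 of 20 cases (mean −0.69, camera adjusted p = 0.0355; adjusted p = 0.462 with an estimated correlation). Their per-array means were 8.87, 7.30 and 7.26 in the DMSO arrays and 8.05, 6.68 and 6.63 in the PHA+ICG arrays, so both arrays numbered 1 stood apart. This call was lost without DMSO replicate 1 (mean −0.16), PHA+ICG replicate 2 (−0.47) or PHA+ICG replicate 3 (−0.44), each of which leaves the other array of its number, and the mean was −1.15 without PHA+ICG replicate 1. Without both arrays numbered 1 the list's mean was −0.63 with 10 members lower, and with replicate number as a block in the second set 13 were lower. On the second set alone limma, without the block, called 0 leukocyte markers, with 4 at an unadjusted p under 0.05, and 10 with the pairs. Camera did not call MET and ERK output genes, of which 5 of 27 fell (mean −0.23, camera adjusted p = 0.076), or Wnt and β-catenin targets, of which 1 of 29 rose and 4 fell (mean −0.11, camera adjusted p = 0.538), with the Wnt antagonist gene Nkd2 at −0.91 ± 0.13. On the second set alone limma called 0 MET and ERK output genes, with 5 at an unadjusted p under 0.05, and 1 Wnt target, Nkd2; with its pairs 5 MET and ERK output genes and 2 Wnt targets were lower. DMSO replicate 1 was at a mean of 9.71 for the MET and ERK genes, against 10.06 and 10.10 in the other DMSO arrays, and camera called the list lower without it (mean −0.36) or without PHA+ICG replicate 3 (−0.27).

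Camera did not call squamous differentiation genes with PHA+ICG (mean −0.36), although Krt6b and the cornified envelope gene Ivl changed by −2.33 ± 0.32 and −2.27 ± 0.22, both also on the second set alone. Their per-array means were 6.28, 7.21 and 7.17 in the DMSO arrays and 7.12, 6.26 and 6.21 in the PHA+ICG arrays. Camera called the list lower without DMSO replicate 1 (mean −0.66), without PHA+ICG replicate 1 (−0.65) and without both (−0.96, 15 of 28 lower), while with the block it stayed uncalled (adjusted p = 0.379). Milk protein and alveolar genes (1 rose and 3 fell of 23) and NF-kB and inflammatory genes (3 rose of 20) were not called either, and on the second set alone limma called 0 members of both, with 4 and 3 at an unadjusted p under 0.05, and 4 (lower) and 1 (higher) with its pairs. The milk protein mean of −0.59 was −0.19 without DMSO replicate 1. With PHA, ICG and PHA+ICG, camera called none of the lists of mammary stem and progenitor genes (means −0.03, 0.04 and −0.15), the CXCL12 and HGF axis (−0.11, 0.01 and −0.43), AhR targets (−0.08, 0.11 and −0.08), endothelial markers (−0.13, 0.02 and −0.07) or adipocyte markers (0.00, −0.08 and −0.35). With replicate number as a block in the second set, camera did call the CXCL12 and HGF axis lower with PHA+ICG, with 5 of 9 members lower, and NF-kB genes higher, with 6 of 20 higher and 1 lower (both at an adjusted p of 0.0318). Camera also called the axis without DMSO replicate 2 (mean −0.53) or 3 (−0.52), whereas without DMSO replicate 1, whose signal was highest, the mean was −0.24. It called NF-kB genes without DMSO replicate 3 (0.22) or PHA+ICG replicate 2 (0.25), while the mean was 0.09 without PHA+ICG replicate 1 and 0.03 without both arrays numbered 1. The adipocyte list stayed uncalled there (adjusted p = 0.218), with 1 of 8 lower and 5 at an unadjusted p under 0.05. Cxcl12, a chemokine of stromal cells, was at −2.02 ± 0.47, with an adjusted p of 0.151 on the second set alone and 9.17e-05 with its pairs. The 3′ minus 5′ difference of Gapdh was 0.182 ± 0.0786 (SD, n = 3) in the DMSO arrays and 0.402 ± 0.305 in the PHA+ICG arrays. On PHA+ICG arrays 1, 2 and 3 it was 0.443, 0.685 and 0.0789. Leaving out both arrays numbered 1 thus keeps the array with the largest Gapdh difference. For Actb that array was at 0.506, against a mean of 0.590 in the DMSO arrays.

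With PHA+ICG, limma called 2413 genes, 811 higher and 1602 lower, of which 95 and 440 changed at least 2-fold. At an unadjusted p under 0.05 there were 4541, and the groups did not overlap for 18.3% of genes, against 10% by chance. With quantile normalization 1478 rose and 1387 fell, and with each array centred on its median 1289 rose and 1254 fell. The median gene SD of the replicates was 0.236 in the second set and 0.107 in the first, and 0.183 in the second with its pairs as blocks, so the second set spread more than the first with or without the pairs. Limma called 368 genes on the second set alone, 87 higher and 281 lower, and 1442 with its pairs, 349 higher and 1093 lower; array weights by set gave 641, and 1548 with the pairs. In simulated data with no change the pooled fit called on average 250.2 genes where arrays were independent and 41.45 where pairs shared their deviations as observed. The count of 2413 therefore does not show a larger response than the 1255 of ICG, and which is larger depends on the fit: without PHA+ICG replicate 1 it was 3517, without both arrays numbered 1 it was 3756, and with replicate number as a block in the second set 4355 against 2709 for ICG, although 616.45 were then called with no change; each set alone gave 368, or 1442 with its pairs, against 4896.

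**Figure D3:**
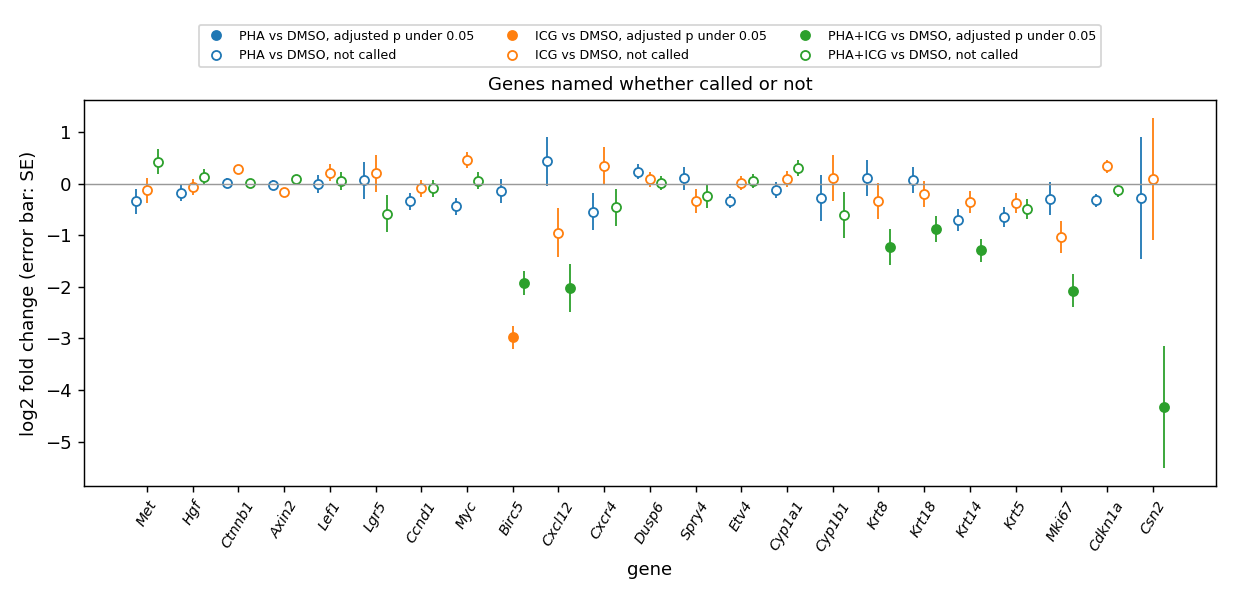
Log2 fold change with SE (vertical axis, n = 3 arrays per group) of 23 genes named in advance (horizontal axis) in PHA, ICG and PHA+ICG against DMSO, with filled points for genes called by limma. Birc5 was at −0.14 with PHA, −2.98 with ICG and −1.93 with PHA+ICG.

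PHA against ICG compares the inhibitors within the first set. Cell cycle genes were higher with PHA than with ICG: Top2a by 3.31 ± 0.30, Rrm2 by 3.30 ± 0.29 and Birc5 by 2.83 ± 0.23. Cth was at −4.14 ± 0.22 (adjusted p = 2.61e-07), Car6 at −3.66 ± 0.48 and the serine synthesis gene Phgdh at −2.87 ± 0.23, all lower with PHA. Of the G1/S genes 20 of 35 were higher (mean 0.94) and of the G2/M genes 23 of 36 (mean 1.20), at adjusted p = 0.00981 and 0.102 with an estimated correlation. ATF4 genes were lower in 21 of 26 cases (mean −1.43) and cholesterol biosynthesis genes higher in 12 of 20 (mean 0.73), both at an adjusted p = 0.00743 with an estimated correlation. Idi1 differed by 1.77 ± 0.12 and Fdps by 1.57 ± 0.17. Of 19 p53 targets 8 were lower with PHA (mean −0.46; adjusted p = 0.11 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a was at −0.65 ± 0.12. Camera also called squamous differentiation genes (2 of 28 lower) and NRF2 targets (2 of 16 higher, 7 lower), both at an adjusted p = 0.532 with an estimated correlation. Fibroblast markers (5 of 16 higher and 1, Mfap5 at −1.40 ± 0.13, lower) were called at a camera adjusted p of 0.0121, but not with an estimated correlation (adjusted p = 0.558), on the first set alone, or without ICG replicate 3 (mean 0.36). Myc was lower with PHA than with ICG, at −0.91 ± 0.16. In all, limma called 1463 genes, 793 higher and 670 lower with PHA, and 4939 on the first set alone, 2497 higher and 2442 lower. The count without a single array was 825 (PHA 1), 858 (PHA 2), 890 (PHA 3), 825 (ICG 2) or 817 (ICG 3).

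Of the genes called with PHA and with ICG, 5 rose and 69 fell in both, where independence would give 0.38 and 7.85, and 8 moved in opposite directions. Across genes, which are not independent replicates, the fold changes had r = 0.39 and rho = 0.34. The 3 DMSO arrays were shared by both comparisons, and 100 simulations with no change gave r = 0.50 from this sharing alone. Their covariance was 0.00606 against 0.0317 observed. They gave 0 shared calls, but with no change the fit called 0 genes with PHA and with ICG. That count therefore cannot show how much the shared DMSO arrays add to the 5 and 69. ICG and PHA+ICG, which share no arrays, had 210 genes higher and 571 lower in both, against 17.1 and 76.7 under independence, with r = 0.62 and rho = 0.52. PHA and PHA+ICG had 3 higher and 61 lower in both, against 0.80 and 14.4, with r = 0.26 and rho = 0.19, and 17 genes moved in opposite directions.

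The effect of PHA+ICG minus the effect of PHA asks what ICG adds, with each effect taken against the DMSO arrays of its own set. The 2 effects were measured in different sets, so a response that differs between sets cannot be told apart from what ICG adds. Car6 was higher by 4.13 ± 0.68, the muscle chaperone gene Unc45b by 3.23 ± 0.39, the neurotensin gene Nts by 3.21 ± 0.44 and Ednrb by 3.13 ± 0.27, and Agtr2 and Aoc3 were at −3.05 ± 0.36 and −2.59 ± 0.35. Cholesterol biosynthesis genes were lower in 16 of 20 cases (mean −1.34, adjusted p = 0.00132 with an estimated correlation), with Tm7sf2, Fdps, Idi1 and Cyp51 at −2.55 ± 0.24, −2.31 ± 0.24, −2.27 ± 0.17 and −2.01 ± 0.30. ATF4 genes were higher in 14 of 26 cases (mean 1.00, adjusted p = 0.0492 with an estimated correlation), with Cth at 2.84 ± 0.31 and Trib3 at 2.44 ± 0.42. G2/M genes were lower in 15 of 36 cases (mean −1.04), ER chaperones in 6 of 18, and NRF2 targets higher in 6 of 16, each at an adjusted p = 0.254 with an estimated correlation. Array weights by set, which allow for the wider second set, gave 1 G2/M gene, 4 ER chaperones and 3 NRF2 targets instead. They still gave 16 cholesterol and 15 ATF4 genes. With the pairs as well they gave 4, 9 (1 of them higher) and 6 (1 of them lower), and 17 of both. In simulated data with shared pairs 37.5% of the PHA+ICG calls of that last fit were false where 200 genes changed. With replicate number as a block in the second set, camera also called luminal and leukocyte markers lower (adjusted p = 0.0441 and 0.000442). In all, limma called 860 genes, 352 higher and 508 lower, 499 with array weights by set, and 1149 with these weights and the pairs of the second set. With quantile normalization 553 were higher and 536 lower. Leaving out 1 array gave 496, 537 and 572 (DMSO 1, 2 and 3 of the first set), 479, 492 and 547 (PHA 1, 2 and 3) or 1530 (PHA+ICG 1).

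The effect of PHA+ICG minus the effect of ICG asks what PHA adds. Here too a response that differs between the sets cannot be told apart from it. Nts was higher by 3.29 ± 0.44, the synaptic scaffold gene Dlg2 by 2.42 ± 0.23 and Mei4 by 2.51 ± 0.38, while Agtr2 and the lipoprotein receptor gene Olr1 were at −3.07 ± 0.36 and −2.77 ± 0.38. Ackr3, a scavenger receptor for Cxcl12, was at −1.76 ± 0.22. Cholesterol biosynthesis genes were lower in 6 of 20 cases (mean −0.61, adjusted p = 0.018 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, at −0.99 ± 0.16. G1/S genes were higher in 3 of 35 cases (mean 0.47, adjusted p = 0.108 with an estimated correlation). Of 26 ATF4 genes 3 were lower and 1 higher (mean −0.44, adjusted p = 0.302 with an estimated correlation), with Asns at −1.19 ± 0.21. With array weights by set, limma called 1 cholesterol gene (Hmgcs1 was at an adjusted p of 0.0587), 3 ATF4 genes and 0 G1/S genes, of which 9 had an unadjusted p under 0.05; with the pairs as well it called 4 (Hmgcs1 among them), 5 and 1. With replicate number as a block in the second set, camera also called milk protein genes, leukocyte and adipocyte markers lower (adjusted p = 0.00768, 0.0254 and 0.0392). In all, limma called 160 genes, 53 higher and 107 lower, against 80 and 93 with quantile normalization and in all 70 with array weights by set and 284 with these weights and the pairs. Leaving out 1 array gave 81, 79 and 78 (DMSO 1, 2 and 3 of the first set), 78, 67 and 78 (ICG 1, 2 and 3), 365, 106 and 94 (DMSO 1, 2 and 3 of the second set) or 470 (PHA+ICG 1).

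Departure from additivity is the effect of PHA+ICG minus the sum of the effects of PHA and ICG on the log2 scale. It rests on both sets, so a response that differs between them cannot be told apart from a departure. Mmp1a was higher than the sum by 4.08 ± 0.34 (adjusted p = 0.000119), Cemip by 4.29 ± 0.44 and Nts by 4.94 ± 0.62. Of 16 fibroblast markers 4 were above the sum (mean 1.45, camera adjusted p = 2.02e-15, adjusted p = 0.0814 with an estimated correlation), with Postn, Col3a1 and Col6a3 at 3.92 ± 0.67, 3.59 ± 0.64 and 2.84 ± 0.44. Genes of cholesterol biosynthesis were below the sum, with 2 of 20 called (mean −0.88, adjusted p = 0.0097 with an estimated correlation), Tm7sf2 at −1.96 ± 0.34 and Hmgcs1 at −1.21 ± 0.22. Egr1 was at −1.82 ± 0.29 and the transcription factor gene Klf2 at −2.05 ± 0.35. The calls of Nts, Cemip and Mmp1a held without each single array, and those of the other genes named here were each lost without at least 1. With array weights by set those of Postn and Col3a1 were lost as well (adjusted p = 0.063 and 0.0512), but with the pairs of the second set they passed (0.0345 and 0.0254), and 5 fibroblast markers were above and 8 cholesterol genes below the sum. In all, limma called 78 genes, 56 higher and 22 lower, and 346 with the weights and the pairs. Without DMSO 1, 2 or 3 of the first set there were 35, 12 and 20, all of them higher. The calls were not mostly higher in each fit: 88 were higher and 94 lower without PHA+ICG 1, 252 and 275 without both arrays numbered 1, and 494 and 723 with array weights. Without another single array there were 49 and 32 (PHA 1 and 2), 50 (ICG 2), 188 (DMSO 1 of the second set) or 182 (PHA+ICG 1).

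The DMSO arrays of the sets, which no treatment separates, differed in 4990 genes, 2636 higher and 2354 lower in the second set (2631 and 2664 with quantile normalization). The matrix protein gene Mgp was higher by 7.84 ± 0.33, Prl8a2 by 7.60 ± 0.15 and the fibulin-like gene Efemp1 by 6.86 ± 0.36. The chemokine gene Cxcl3 was at −8.18 ± 0.18, the neutrophil protein gene S100a9 at −6.92 ± 0.36 and the platelet factor gene Pf4 at −5.83 ± 0.17. In the second set cholesterol biosynthesis genes were higher in 18 of 20 cases (mean 1.79, adjusted p = 0.00909 with an estimated correlation). NF-kB and inflammatory genes were lower in 14 of 20 cases (mean −1.28, adjusted p = 0.0223 with an estimated correlation) and interferon response genes in 15 of 22 (mean −1.09, adjusted p = 0.0268 with an estimated correlation). Leukocyte markers were lower in 13 of 20 cases (mean −1.68, adjusted p = 0.362 with an estimated correlation) and squamous genes in 15 of 28 (mean −0.94, adjusted p = 0.419 with an estimated correlation). Fibroblast markers were higher in 11 of 16 cases and lower in 1 (mean 1.65, adjusted p = 0.295 with an estimated correlation), and G2/M genes higher in 24 of 36 (mean 0.86, adjusted p = 0.503 with an estimated correlation). Where PHA+ICG is compared with arrays of the first set, the set and the combination cannot be told apart. The same holds where its effect is compared with those of PHA and ICG, because subtracting DMSO does not remove a response that depends on the set.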

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

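The matched lists for cholesterol genes were planned before their result was seen; the tests of normalization, of fibroblast loss, of the arrays numbered 1, and the counts of other splits were chosen after the results were seen.

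Camera at its preset correlation called these gene groups in opposite directions for 2 treatments, and called the difference. Between PHA and ICG, the difference of the mean log2 fold change was −0.456 for p53 targets, −1.43 for ATF4 genes and 0.73 for cholesterol biosynthesis genes. Between PHA+ICG and PHA it was 0.34 for p53 targets, 1.00 for ATF4 genes, −1.34 for cholesterol biosynthesis genes and 0.31 for MYC and ribosome biogenesis genes; that of p53 targets was 0.18 without PHA+ICG replicate 1. With an estimated correlation the differences of p53 targets (adjusted p = 0.11 and 0.254) and of MYC genes (adjusted p = 0.324) were lost, and those of ATF4 and cholesterol genes held. Each opposing pair also held a call that was lost: p53 targets in all 3 treatments (adjusted p = 0.425, 0.356 and 0.415 for PHA, ICG and PHA+ICG), MYC genes with PHA and PHA+ICG (0.513 and 0.415), ATF4 genes with PHA and PHA+ICG (0.425 and 0.142), and cholesterol genes with PHA (0.13). Single genes called in opposite directions with a called difference numbered 8 between PHA and ICG: Aldh18a1, Cyp27b1, Dzip1, Fads2, Idi1, Lims2, Slc43a3 and Stc2. They numbered 17 between PHA and PHA+ICG, among them Tm7sf2, Idi1, Fads2, Timp1 and Fez1, and 13 between ICG and PHA+ICG, among them Ackr3, Klf2, Olr1 and Nts. Outside the named genes, 18 of 9160 probe sets with no gene symbol passed the threshold with PHA, 94 with ICG and 173 with PHA+ICG. Fitted on their own set alone these were 71, 278 and 31, and with array weights by set 151, 638 and 12; the block in the second set gave 424 with PHA+ICG.

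G2/M and G1/S genes were lower with ICG. After quantile normalization of all arrays the G2/M mean was −1.22. The first set's array medians already lay between 5.73 and 5.76, so this step could change little and cannot decide about normalization. Fibroblasts could have been lost from the spheres with their cell cycle transcripts, since fibroblast markers had a mean of −0.82 ± 0.20 (SE over arrays, n = 3) with PHA and −1.34 ± 0.26 with ICG. In that proportion the G2/M mean with PHA would be −0.776, and it was −0.0605 ± 0.253, but the fibroblast markers fell by unlike amounts with ICG (SD 0.81), so these genes may have changed without a change in cell number and the test cannot decide. An effect of ICG on cycling cells therefore stays open beside a loss of a cycling cell type.

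Cholesterol biosynthesis genes were called higher with PHA, where 2 of 20 members passed and the call was lost with an estimated correlation (adjusted p = 0.13), and lower with PHA+ICG, where it held. The list started higher in the DMSO arrays of the second set, and genes with a high start may fall for that reason alone, yet among 10000 lists matched for the difference between the DMSO arrays a share of 0.00090 had a mean as low as −1.07 (matched mean −0.52, lowest −1.20). These lists were drawn gene by gene, so their means vary less than those of a list whose members move together. The share may therefore be too small, and the test cannot exclude the start as the cause. The difference between the effects of PHA+ICG and PHA was −1.43 without both arrays numbered 1 of the second set, which argues against these arrays as the cause. It was −1.28 after quantile normalization, but the deposited values looked already normalized, so this is a weak test of normalization. A response of sterol synthesis that differs between the inhibitors is a hypothesis from these data, and the combination was measured in the second set alone.

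Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 highest of 10 for PHA (182 genes, next highest 0), for ICG (1255 and 0), for PHA against ICG (1463 and 0), for DMSO between sets (4990 and 0) and for PHA+ICG (2413 and 1423). The 1423 came from the split that set DMSO 1, PHA+ICG 1 and PHA+ICG 3 against the others, which keeps both arrays numbered 1 together and so points to a structure of the samples. Of the splits that part all 3 same-numbered pairs as the real one does, the others gave 0, 0 and 19, and a fit with replicate number as a block gave 4355 over all arrays and 1442 on the second set alone. For PHA+ICG minus PHA, 1 of 100 splits gave as many genes as the real 860 (highest other 784). The 10 other splits that kept PHA+ICG apart from its DMSO arrays gave 389 to 784, and the 29 that mixed them while parting all 3 pairs gave 13 at most. Splits that mix arms also mix their treatment effects into the spread within groups, so this share cannot exclude chance for the count. Splits that mixed PHA with DMSO came close to the count, so it owes much to the effect of PHA+ICG itself. It was 499 with array weights by set and 1149 with the pairs as well. For the departure from additivity 3 of 100 gave as many as 78. The highest other, 421, came from a split in which the ICG arrays stood as controls. All 54 splits that mixed the arms of the second set but left a pair together gave 0. Of the 33 that mixed them while parting all pairs, 2 gave at least 78. The share over all splits therefore cannot exclude chance. The count of 421 is several times the real one, but with ICG arrays as controls the effect of ICG enters it. It does not by itself show a structure of the samples, and its cause was not tested. For PHA+ICG minus ICG 9 of 100 gave as many as 160. The highest other, 3270, exchanged PHA+ICG with its DMSO arrays, which adds the effects that the real split subtracts. That count therefore holds treatment effects and is no measure of chance. Of the 10 other splits that kept PHA+ICG apart from its DMSO arrays, 6 gave at least 160, and these also carry its effect. Among the 60 that mixed them but left a pair together, 2 did. The share therefore cannot decide about chance, which cannot be excluded.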

How the results depend on the processing

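Array weights by set, the replicate block in the second set alone, and leaving out both arrays numbered 1 of the second set were chosen after the data were seen. Counts of called genes stayed within 1.5 times under median centring, quantile normalization, the trended robust fit and the mean of a gene's probe sets. They moved with settings that change the spread, which is 2.22 times as large in the second set, and 1.72 times with its pairs blocked. Fitted on its own set alone, each comparison gave 1858 genes (PHA), 4896 (ICG), 368 (PHA+ICG) and 4939 (PHA against ICG); a fit across sets has no such value. Weights estimated for each array were 0.161, 0.119 and 2.72 for PHA+ICG arrays 1, 2 and 3. That fit therefore rests mostly on array 3 for this group. Array weights gave 2156, 4802, 4472 and 5160 for those 4 comparisons and 3449 for PHA+ICG minus PHA. They gave 1647 for PHA+ICG minus ICG, 1217 for the departure from additivity and 8274 for DMSO between sets. Array weights by set gave 1821, 4801, 641, 4789, 499, 70 and 131 in the same order without the last. With the pairs of the second set as well they gave 1548 (PHA+ICG), 1149 (minus PHA), 284 (minus ICG) and 346 (additivity), and the second set alone gave 1442 (PHA+ICG). The replicate block gave 430 (PHA), 2033 (ICG), 2222 (PHA against ICG), 1684 (minus PHA), 431 (minus ICG) and 226 (additivity). The block in the second set gave 666 (PHA), 2709 (ICG), 4355 (PHA+ICG), 2850 (PHA against ICG), 2312 (minus PHA), 729 (minus ICG) and 424 (additivity). Without both arrays numbered 1 there were 3756 (PHA+ICG), 2174 (minus PHA), 951 (minus ICG) and 527 (additivity). With all 6 DMSO arrays as control PHA gave 53, and without dim genes additivity gave 50, with fewer genes tested. Leaving out 1 array, which leaves fewer samples, gave 75 to 123 (PHA), 667 to 936 (ICG), 1887 to 3517 (PHA+ICG), 817 to 1023 (PHA against ICG), 479 to 1530 (minus PHA), 67 to 470 (minus ICG), 12 to 188 (additivity) and 3745 to 5659 (DMSO). Genes called the same way with PHA and ICG numbered 74, and 27 with a fold-change minimum, 782 on their own set and 737 with weights by set; for PHA and PHA+ICG 64, 24 with the minimum and 124 with weights by set; for ICG and PHA+ICG 781, 166, 291 on their own sets and 499. With all 6 DMSO arrays as control, a setting that mixes the sets, Idi1 (−1.18) and Fads2 (−0.46) reversed for PHA, and Egr1 (−0.0312) and Plaur (0.38) for ICG. For PHA+ICG so did Apcdd1 (0.93), Aldh1a1 (0.35), Idi1 (0.29), Csf3 (−0.60), Fap (0.42), Dpt (1.502) and Mfap5 (0.17). The squamous list reversed for PHA+ICG minus PHA without both arrays numbered 1 (−0.47), and for PHA+ICG minus ICG camera's direction of the leukocyte list, uncalled at first, turned to lower under both blocks with the same mean (−0.11). Of 74 list calls outside the DMSO comparison, camera with an estimated correlation kept 12, fry 38, quantile normalization 72, the filter on dim genes 60 (7 of 11 with PHA) and the replicate block 74, and the others kept their direction but not their call. Of the named genes called, those also called on their own set numbered 24 of 24 (PHA), 53 of 53 (ICG), 45 of 95 (PHA+ICG, 80 with its pairs) and 50 of 50 (PHA against ICG). Apart from the spread, the fewer genes, the fewer samples and the mixed sets, the cause was not tested. The alternative floors for linear values did not apply. Signals near background limit what weakly expressed genes can show.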

Other observations

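The test of mast cell and basophil markers was written before its result was seen, after Fcer1a, Mcpt8 and Tph1 had been found lower with PHA.

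These 3 genes, known from mast cells and basophils, had a mean log2 fold change of −2.45 with PHA. A smaller share of such cells could lower them, and would lower other markers of these cells alike. Of 24 markers written down, 20 were measured and 9 had a mean above 6.97, the median of all genes, in the DMSO arrays of the first set; some of them, such as Srgn, Kit and Gata2, are also expressed by other cells. The mean of these 9 was −0.65 ± 0.19 (SE over genes) with PHA, with 3 called lower: Tpsb2 at −1.51, Cma1 at −1.22 and Hdc at −0.93. The camera p was 5.06e-09, and p = 0.000301 with an estimated correlation. Cpa3, an abundant mast cell protease gene at a mean of 10.6 in those arrays, was at 0.21 ± 0.29. Both outcomes written beforehand were met. Camera placed the set lower, which a smaller share of these cells predicts. The mean of −0.65 also lay above the midpoint of 0 and −2.45 by more than 2 SE, which had been written as speaking against it. However, the 3 genes were picked among the lowest with PHA in these same arrays, so other markers could fall less for that reason alone. The test therefore cannot decide whether a smaller share of these cells was the cause. The same markers had a mean of −0.33 with ICG and −0.73 with PHA+ICG.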
